A study of Mus musculus with 15 samples.

How the data were processed

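Polyadenylated RNA from libraries of 15 mouse GV oocytes was prepared with the QIAseq FX Single Cell RNA kit, per the labels' protocols. Groups were taken from the titles and genotype labels. Names in brackets in the titles say WT where the title and the genotype say heterozygote, and the groups are called het here. The authors deposited, for each library, whole-number counts of reads per gene, not normalised. Reads were demultiplexed with bcl2fastq 2.20.0.422, trimmed with cutadapt 2.8, aligned with STAR 2.7.8a and counted with HTSeq 2.0.2 against mm39, as far as the names of these tools in the submitters' processing notes tell. The annotation release and the strand setting of the counting are not given in the sources used here, so counts of overlapping and antisense genes are uncertain. Reads aligned to several places were set apart in the deposited counts, so families of near-identical genes are uncertain too.

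Each deposited table held 53700 genes and 92 spike-in transcripts, plus summary lines for reads not assigned to a gene. Reads outside any gene were 5.39 to 7.29% of all reads in a library's table, reads in overlapping genes 3.85 to 4.2% and reads with several alignments 12.09 to 14.51%. Spike-ins and summary lines stayed out of library sizes and tests. Gene symbols came from GENCODE M21, which is on GRCm38, and 52147 identifiers were matched while 1553 were not. Because the builds differ, that annotation served for names, gene types, chromosome, gene order and GC content only, and no coordinates are given.

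Technical libraries A and B of a biological replicate were added together, giving 3 het and 3 KO replicates in the Padi6 line and 2 het and 4 KO replicates in the Tle6 line. Genes passing filterByExpr were tested with edgeR 4.0.16 (R 4.3.3, TMM scaling, glmQLFit with robust estimation, glmQLFTest, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Each line was fitted by itself, so that the spread was estimated within a line, since the lines differ in strain background. The difference between the lines' effects was an interaction contrast over all 12 biological replicates, with the spread of each gene shared by both lines. CPM per library are counts-per-million of the library's gene counts, and group means of CPM use TMM-scaled library sizes (those of the difference were scaled over both lines together). For a gene with 3 counts or fewer in a group, the ratio is given with its exact binomial counting interval at 95%, which covers counting error only, as reads are not independent molecules. Depths of 30100177 to 74947533 counts per library leave the spread between replicates, not counting, as the limit for most named genes. The common biological coefficient of variation was 0.203 in the Padi6 line and 0.361 in the Tle6 line.

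The tests, the groups, the alternatives, the gene lists and the naming rule were fixed before the data were examined. The rule names Padi6 and Tle6, the members of the subcortical maternal complex and lattice list, and per line the 10 higher and 10 lower genes with the largest fold change. These must be past the threshold, at 10 CPM or more in the higher group, without overlap between the groups' replicates, protein-coding, and with a symbol that is not a Gm or Rik name. It adds up to 3 called members of each list by smallest p, the genes called in both lines in the same direction, and the 10 genes with the smallest p in the difference.

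The 23 lists were the subcortical maternal complex and lattice, the NLRP family of the oocyte, DNA methylation and imprint maintenance, SCF ubiquitin ligases and E2 enzymes, tubulins, oocyte identity, maternal mRNA storage and decay, meiotic maturation and cell cycle, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, the unfolded protein and heat shock response, the proteasome, autophagy and lysosome, p53 targets and DNA damage, early embryo (2-cell) transcripts, imprinted genes, small RNA pathways, the oocyte actin cytoskeleton, the PADI family, granulosa and cumulus cells, theca and stroma cells, and blood and immune cells. Lists with at least 3 measured members were tested with camera (limma 3.58.1, preset correlation 0.01, log2 CPM with a prior count of 2), again with an estimated correlation, and with fry. Shares of counts and summed CPM were compared with two-sided exact permutation tests, which in 3 against 3 cannot give a p below 0.1 and in 4 against 2 none below 0.067.

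Alternatives were RLE, upper quartile or total count scaling, no filter or a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom, a 2-fold minimum, a spread shared by both lines, a block for the replicate number, counts thinned to the lowest total, mitochondrially encoded genes left out, other uses of the technical libraries, and each biological replicate left out in turn. Leaving out either library of Tle6 het replicate 2, or keeping them as separate replicates, and removing each library's GC trend were added after the data had been seen.

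The steps were tested on simulated counts drawn from the real means, spreads and library sizes. Of genes changed by 2-fold and 4-fold, edgeR recovered 63% and 96% in the Padi6 line (17826 genes), 14% and 89% in the Tle6 line (19668 genes) and 10% and 68% for the difference (20671 genes). Unchanged genes made up 11 of 170 calls in the Padi6 line, 12 of 115 in the Tle6 line and 3 of 81 for the difference. For the difference both lines were drawn with the same spread per gene, unlike the real lines. Its recovery and its 3 of 81 therefore cannot show how the test behaves when the spreads differ. Changed genes were not drawn from those at the lowest expression, so recovery there is not covered. In the simulated Padi6 and Tle6 lines camera called the moved list and 0 others. Genes were drawn independently there, so this cannot show how often camera calls a list whose members vary together. In the real Padi6 line the estimated correlation was 0.237 for the mitochondrially encoded genes. Plots were drawn with matplotlib 3.10.9 in python 3.11.15.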

Results

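RNA was sequenced from mouse oocytes at the germinal vesicle (GV) stage, fully grown oocytes that have not yet resumed meiosis, in libraries of 15 oocytes each. In the Padi6 line, on the FVB/N background, 3 libraries came from heterozygotes (het) and 3 from knockouts (KO). In the Tle6 line, on the C57BL/6J background, 2 het and 4 KO biological replicates were sequenced. Het replicates 1 and 2 and KO replicate 4 of this line each had technical libraries A and B, whose counts were added before testing. PADI6, a peptidylarginine deiminase, and TLE6, a subunit of the subcortical maternal complex, are both known to be needed for the cytoplasmic lattices, fibrous arrays in the oocyte cytoplasm. The comparisons ask which transcripts differ in oocytes that lack either gene, and whether the same transcripts differ in both.

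Counts in genes ranged from 30100177 to 74947533 per library. Het replicates 1, 2 and 3 of the Padi6 line had 49833344, 48109665 and 60316140, and KO replicates 1, 2 and 3 had 70204655, 60966380 and 45708084. Tle6 het replicate 1 had 52538288 in library A and 37385610 in library B, and het replicate 2 had 40731634 and 74947533. Tle6 KO replicates 1, 2 and 3 had 45530698, 59311417 and 72706946, and KO replicate 4 had 50524234 and 30100177. Mitochondrially encoded genes took 0.703% ± 0.108 (SD, n = 3) of the counts in Padi6 KO and 0.87% ± 0.12 (n = 3) in Padi6 het (two-sided exact permutation test, p = 0.3, where 0.1 is the smallest p possible). They took 0.354% ± 0.13 (n = 4) in Tle6 KO and 0.27% (n = 2) in Tle6 het (exact p = 0.467, smallest possible 0.067). In libraries A and B the share was 0.26 and 0.28% for Tle6 het replicate 1 but 0.35 and 0.19% for het replicate 2. Tle6 KO replicates 1, 2 and 3 had 0.22, 0.47 and 0.46%, and the libraries of KO replicate 4 had 0.26 and 0.27%. Transcripts of the granulosa and cumulus cell list, the cells that surround the oocyte, summed to 747 ± 42.6 CPM (counts-per-million of all gene counts) in Padi6 KO and 781 ± 41.7 in Padi6 het (n = 3 each, exact p = 0.5). They summed to 598 ± 170 CPM (n = 4) in Tle6 KO and 539 ± 104 (n = 2) in Tle6 het (exact p = 0.6). These means join unlike libraries. The sum was 463 and 467 CPM for het replicate 1, 454 for KO replicate 1, and 442 and 457 for KO replicate 4. It was 759 and 731 CPM for KO replicates 2 and 3, and 709 and 516 CPM for libraries A and B of het replicate 2. Low and high sums thus occurred in both genotypes. Theca and stroma transcripts summed to 40.9 ± 4.48 and 45.5 ± 4.82 CPM in Padi6 KO and het (n = 3 each, exact p = 0.3), and to 37.0 ± 4.73 (n = 4) and 41.2 ± 3.08 (n = 2) in Tle6 KO and het (exact p = 0.333). Blood and immune transcripts summed to 5.28 ± 1.12 and 6.55 ± 1.49 CPM in Padi6 KO and het (n = 3 each, exact p = 0.4), and to 12.3 ± 3.97 (n = 4) and 8.27 ± 2.38 (n = 2) in Tle6 KO and het (exact p = 0.333).

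Libraries A and B correlated at r = 0.998 across genes for Tle6 het replicate 1 and again for KO replicate 4, but at 0.901 for het replicate 2. Biological replicates of the same group correlated at 0.981 to 0.991 in the Padi6 line and at 0.923 to 0.988 in the Tle6 line. Het libraries correlated with KO libraries at 0.969 to 0.984 in the Padi6 line and at 0.887 to 0.955 in the Tle6 line, which overlaps the values within groups. Tle6 het replicate 1 correlated at 0.943 to 0.955 with KO replicates 1 and 4, at 0.923 to 0.94 with het replicate 2 and at 0.912 to 0.92 with KO replicates 2 and 3. Among Tle6 KO libraries, replicates 1 and 4 correlated at 0.986 to 0.988 and replicates 2 and 3 at 0.988, but those pairs with each other at 0.957 to 0.965. Il20ra, which encodes a cytokine receptor chain, had 161 CPM in library A and 0.0267 CPM in library B of het replicate 2. The leading counts that use the Tle6 line are therefore also given without library B of that replicate. The labels call the replicates biological but do not say which animals the oocytes came from, so p-values measure the spread between these samples.

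Each targeted transcript was reduced in the libraries labelled knockout. Padi6 was at 1852, 1756 and 1737 CPM in the 3 Padi6 het libraries and at 26.6, 24.8 and 19.3 CPM in the 3 Padi6 KO libraries, and at 1410 to 2637 CPM throughout the Tle6 line. Its log2 fold change was -6.22 ± 0.14 (SE, adjusted p = 1.24e-08). Tle6 was at 418 and 378 CPM in libraries A and B of Tle6 het replicate 1 and at 600 and 234 CPM in those of het replicate 2. In Tle6 KO it was at 85.9, 79.1 and 61.5 CPM in replicates 1, 2 and 3 and at 98.2 and 89.0 CPM in the libraries of replicate 4. Its log2 fold change was -2.40 ± 0.21 (SE, adjusted p = 1.67e-03), and it stood at 1067 to 1417 CPM in the Padi6 line. What part of either gene was removed is not given in the sources used here, so the remaining counts do not show whether a protein could be made.

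**Figure D1:**
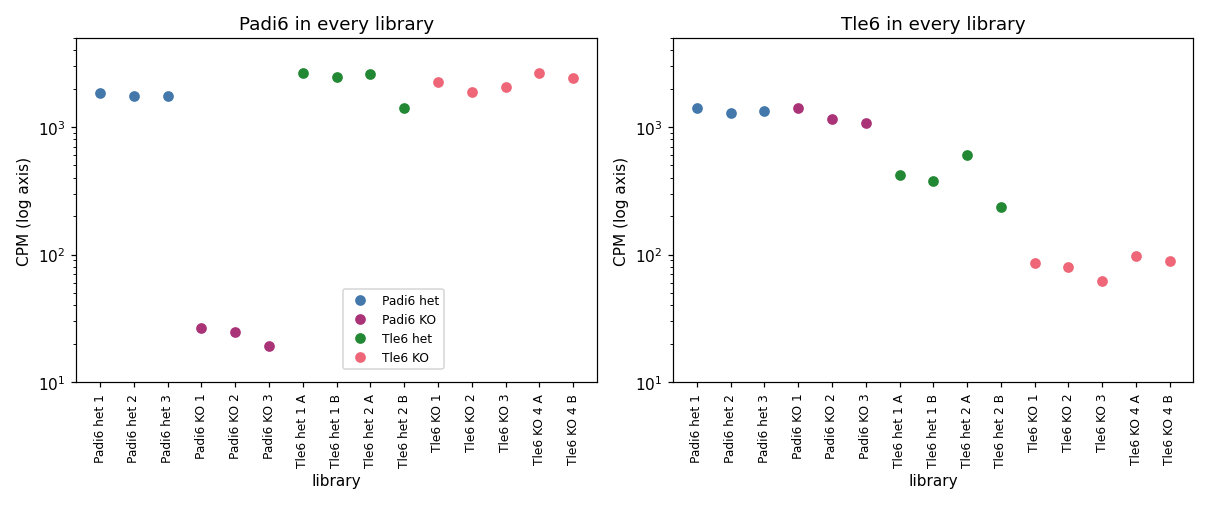
CPM (log axis) of Padi6 (left) and Tle6 (right) in each of the 15 libraries, with 1 point per library coloured by group. Padi6 lies between 19.3 and 26.6 CPM in the Padi6 KO libraries and at 1410 CPM or more elsewhere, and Tle6 lies between 61.5 and 98.2 CPM in the Tle6 KO libraries and at 234 CPM or more elsewhere.

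In Padi6 KO oocytes, 308 genes were higher and 132 lower than in Padi6 het oocytes. Apart from Padi6 itself, Plac1, a gene best known from placenta, had the largest change among the named genes, from 1.59 ± 0.687 to 16.1 ± 5.38 CPM (SD, n = 3 each, log2 fold change 3.35 ± 0.36 SE, adjusted p = 4.30e-03). Prrx1, a homeobox transcription factor of mesenchyme, rose from 6.38 ± 1.2 to 31.3 ± 1.08 CPM (log2 fold change 2.29 ± 0.16, adjusted p = 3.42e-04). Gli2, a transcription factor of the Hedgehog pathway, rose by 2.18 ± 0.31 on the log2 scale, and Has2, a hyaluronan synthase active in cumulus cells, by 2.19 ± 0.31. Both stood at low levels, with Has2 at 11.6 ± 0.514 CPM in KO and 2.55 ± 1.21 CPM in het.

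The other higher genes named by the rule were Ahi1, which acts at the base of cilia (log2 fold change 2.31), Selenop, which carries selenium (2.22), Meioc, a regulator of meiotic prophase (1.82), the deubiquitinase gene Stambpl1 (1.80), Arrdc3 (1.73) and Dirc2 (1.72, and 2.43 without het replicate 2). Among genes lower in Padi6 KO, Haus8, a subunit of the augmin complex that nucleates spindle microtubules, fell from 17.0 ± 8.03 to 4.79 ± 0.696 CPM (log2 fold change -1.82 ± 0.30, adjusted p = 0.0181). Log2 fold changes were -1.44 for Cmklr1, a chemokine-like receptor gene, -1.19 for the histone gene Hist1h2bc, -1.12 for Wdr24, a regulator of mTORC1, and -1.09 for the RNA-binding protein gene Bicc1. They were -1.09 for Zfp770, -1.04 for the recombination gene Rad51d, -0.97 for the cilium gene Cfap45 and -0.92 for the phosphatase gene Ppm1l. For each gene in this and the preceding paragraph the 3 KO values lay outside the range of the 3 het values. The naming rule requires this, so it adds no support.

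Other members of the subcortical maternal complex did not pass the test in Padi6 KO oocytes. The list of this complex and the lattices had 9 measured genes, of which Padi6 was lower and 8 did not pass, with 1 lower when adjusted over the list alone. Log2 fold changes were -0.27 ± 0.11 (SE) for Nlrp5, -0.24 ± 0.11 for Nlrp14, -0.23 ± 0.10 for Nlrp2, -0.12 ± 0.11 for Tle6 and -0.07 ± 0.11 for Nlrp4f. They were 0.25 ± 0.13 for Ooep, 0.20 ± 0.12 for Zbed3 and 0.30 ± 0.25 for Khdc3, which ran from 0.07 without het replicate 1 to 0.61 without het replicate 2. Ooep stood at 10110 ± 1255 CPM in KO and 8534 ± 1016 CPM in het (n = 3 each). The PADI family list likewise held Padi6 as its lower gene and 4 genes that did not pass, with 1 adjusted over the list alone. In the NLRP family of the oocyte, 12 genes were measured and none passed (0 adjusted over the list alone); 10 had negative values, with a median of -0.19.

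Mitochondrially encoded genes were lower in Padi6 KO as a list (camera with a preset correlation of 0.01, adjusted p = 0.0156). The list's call was lost with an estimated correlation (adjusted p = 0.668) and was not made by fry, which tests whether a list's own genes move on balance in the same direction (adjusted p = 0.1385). Of the 11 measured, 9 had negative values, the median log2 fold change was -0.43, and mt-Nd1, a subunit gene of respiratory complex I, fell from 244 ± 7.98 to 177 ± 8.03 CPM (-0.47 ± 0.09, adjusted p = 0.0283). The other 10 did not pass over all genes, and 6 were lower when adjusted over the list alone: mt-Nd1, mt-Nd2, mt-Co1, mt-Nd4, mt-Nd6 and mt-Cytb. Across the alternatives the list's adjusted p ranged from 3.11e-04 to 0.668. Without het replicate 1 it was 0.0603 and without KO replicate 3 it was 0.0701. Nuclear-encoded genes of oxidative phosphorylation had 74 measured members, none past the test (0 adjusted over the list alone) and a median of -0.01.

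No other list passed camera in the Padi6 line, where 1 of 22 lists passed and 5 had an unadjusted p under 0.05. Single members still changed. In the list of maternal mRNA storage and decay, 1 of 31 genes rose, 1 fell and 29 did not pass (1 higher and 1 lower adjusted over the list alone). The risen gene was Zfp36l2, whose protein promotes decay of AU-rich transcripts, at 63.5 ± 10.9 CPM against 27.9 ± 4.12 (log2 fold change 1.19), and Igf2bp3 fell by 0.53 on the log2 scale. Of 27 genes of the unfolded protein and heat shock response, the chaperone genes Hspb1 and Dnajb9 rose by 1.49 and 0.74, the stress-response transcription factor gene Atf4 fell by 0.68, and 24 did not pass (2 higher and 1 lower adjusted over the list alone). Of 17 p53 targets, the kinase gene Plk2 rose by 0.95 and 16 did not pass, and 4 were higher when adjusted over the list alone, Ccng1, Btg2, Plk2 and Sesn1 (camera adjusted p = 0.156). Tubb5 rose by 0.43 among 16 tubulins, with 15 not past the test (1 higher adjusted over the list alone). Smc1b, a cohesin subunit specific to meiosis, fell by 0.49 among 33 genes of meiotic maturation, with 32 not past (1 lower adjusted over the list alone).

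Fbxw13 fell by 0.56 among 33 genes of SCF ubiquitin ligases and E2 enzymes, with 32 not past (1 lower adjusted over the list alone). Usp17le had a log2 fold change of 2.74 (3.39 without het replicate 1) among 11 transcripts of the 2-cell embryo, with 10 not past (1 higher adjusted over the list alone). Both belong to families of near-identical genes and are uncertain, because reads that matched several places were left out of the counts. Among 24 imprinted genes, Phlda2 rose by 1.00 and 23 did not pass, while adjusted over the list alone Phlda2 and Zim1 were higher and Igf2r lower. Has2 was the risen gene of 19 granulosa and cumulus genes, of which 18 did not pass and 15 had negative values (median -0.51, camera adjusted p = 0.326). Adjusted over the list alone, Amhr2, Cyp11a1, Fshr and Inha were lower and Has2 higher. Cyp11a1, which makes pregnenolone, stood at 3.46 ± 0.597 CPM in KO and 12.1 ± 10.01 in het.

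Of 20 genes of DNA methylation and imprint maintenance none passed over all genes, and Dnmt3l and Zfp445 were lower when adjusted over the list alone (2 of 20). Of 29 oocyte identity genes none passed, and Kit and Sohlh1 were lower when adjusted over the list alone. Of 7 theca and stroma genes none passed, with Ptch1 higher and Pdgfra lower adjusted over the list alone. No member passed either way among 82 cytosolic ribosomal protein genes, 42 proteasome genes, 27 autophagy and lysosome genes, 26 genes of small RNA pathways, 25 genes of the oocyte actin cytoskeleton and 2 blood and immune genes. Camera's adjusted p was 0.294 for the ribosomal proteins, 0.756 for the proteasome, 0.447 for autophagy and lysosome, 0.756 for small RNA pathways and 0.756 for actin. The blood list had too few measured genes for a list test. With fry, the lists holding Padi6 passed (adjusted p = 6.24e-05 for the subcortical maternal complex and 7.19e-05 for the PADI family).

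In this comparison edgeR's quasi-likelihood test covered 18228 genes, of which 440 had a Benjamini-Hochberg adjusted p under 0.05 and 3399 an unadjusted p under 0.05. The count of 440 depended on single replicates, being 254, 231 and 61 without het replicate 1, 2 or 3 and 258, 90 and 77 without KO replicate 1, 2 or 3, and 12 to 22 of the 33 named genes past the test lost their call on leaving out a replicate. It was 1322 with DESeq2, 1625 with no filter on low counts, 262 with at least a 2-fold change required and 60 with a spread shared by both lines.

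In Tle6 KO oocytes, 119 genes were higher and 210 lower than in Tle6 het oocytes, many of them by large factors. Stk36, a kinase gene linked to Hedgehog signalling and motile cilia, stood at 232 ± 34.9 CPM (SD, n = 4) in KO and 12.5 ± 1.86 CPM (n = 2) in het (log2 fold change 4.21 ± 0.26 SE, adjusted p = 2.37e-04). Gpat3, which makes lysophosphatidic acid for lipid synthesis, stood at 6.33 ± 5.96 CPM in KO and 217 ± 49.8 CPM in het (-5.11 ± 0.64, adjusted p = 7.28e-03). Il20ra had 1 count over the KO replicates and 28377 over the het replicates, a ratio of 39860 with a counting interval of 7154 to 1575000 at 95%. Its fitted log2 fold change of -14.86 was -13.51 without het replicate 1, -15.54 without het replicate 2 and -16.57 without KO replicate 3. Of the Il20ra counts in het replicate 2, 6566 came from library A and 2 from library B. Without library A that replicate therefore stood near 0, as the KO replicates did, and the change rested on het replicate 1. Without library B of het replicate 2 the comparison gave 50 higher and 70 lower genes, 107 of them shared with the 329 found with it, and without library A it gave 126 and 190, with 248 shared.

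Myo10, an unconventional myosin that binds actin, rose from 42.8 ± 15.7 to 325 ± 93.8 CPM (log2 fold change 2.92 ± 0.36, and 3.97 without library B of het replicate 2), and Haus8 from 4.94 ± 2.02 to 56.7 ± 8.68 CPM (3.52 ± 0.32). The inducible heat shock gene Hspa1b rose by 2.77 on the log2 scale, although it has a near-identical neighbour and its counts are uncertain. D5Ertd577e, from a family of similar genes and also uncertain, was at 42.1 ± 7.004 CPM in KO and 0.200 ± 0.134 CPM in het (log2 fold change 7.68 ± 0.47). Plcl1, related to phospholipase C, was at 12.9 ± 1.39 CPM in KO and 0.0522 ± 0.0738 CPM in het (log2 fold change 7.81). Coro2b, an actin-binding coronin gene, rose by 6.73, the uroplakin gene Upk3b by 2.79 and the lysosomal chloride transporter gene Clcn7 by 2.68. The defensin gene Defb41 had 3523 counts over the KO replicates and 1 over the het replicates, a ratio of 2508 with a counting interval of 449.8 to 99090. Single het replicates set some of these sizes: log2 fold changes without het replicate 1 were 6.91 for Plcl1 and 6.05 for Coro2b, and without het replicate 2 they were 12.82, 8.25 and, for D5Ertd577e, 8.58. The fitted value of Defb41, 10.86, was 12.90 without het replicate 1 and 9.86 without het replicate 2. Leaving out library B of het replicate 2 gave 5.93 for Coro2b and 2.07 for Clcn7, and without library A they were 8.63 and 3.31, with 9.65 for Plcl1.

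Among genes lower in Tle6 KO, Arid5b, a chromatin-binding protein gene, was at 4.92 ± 6.60 CPM in KO and 143 ± 9.999 CPM in het (log2 fold change -4.88 ± 0.92, adjusted p = 0.0399). H2-Aa, a class II histocompatibility gene, was at 1.66 ± 0.421 CPM in KO and 22.7 ± 9.39 CPM in het (-3.78 ± 0.33, adjusted p = 1.67e-03). Log2 fold changes were -6.15 for Pknox2, -4.29 for Meiob, which acts in meiotic recombination, -4.27 for Smg9, a factor of nonsense-mediated decay, -3.19 for Gpaa1, which attaches GPI anchors, and -3.18 for the septin gene Sept3. Skint5, from a family of similar genes, had 2 counts over the KO replicates and 2572 over the het replicates, a ratio of 1806 with a counting interval of 499.6 to 14920. Its 989 counts in het replicate 2 all came from library A, with 0 in library B, and without library A it did not pass the filter for testing in this line. Smg9 was at -2.84 without het replicate 1 and -5.01 without het replicate 2, and Gpaa1 at -2.47 without het replicate 1. Without KO replicate 1, Pknox2 was at -8.39, Gpat3 at -6.03 and Arid5b at -6.47. Without library B of het replicate 2, Clcn7, Pknox2, Arid5b, Smg9, H2-Aa, Gpaa1, Smc1b and Dclk3 kept their direction and lost their call, with adjusted p from 0.0574 for Dclk3 to 0.147 for Gpaa1.

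**Figure D2:**
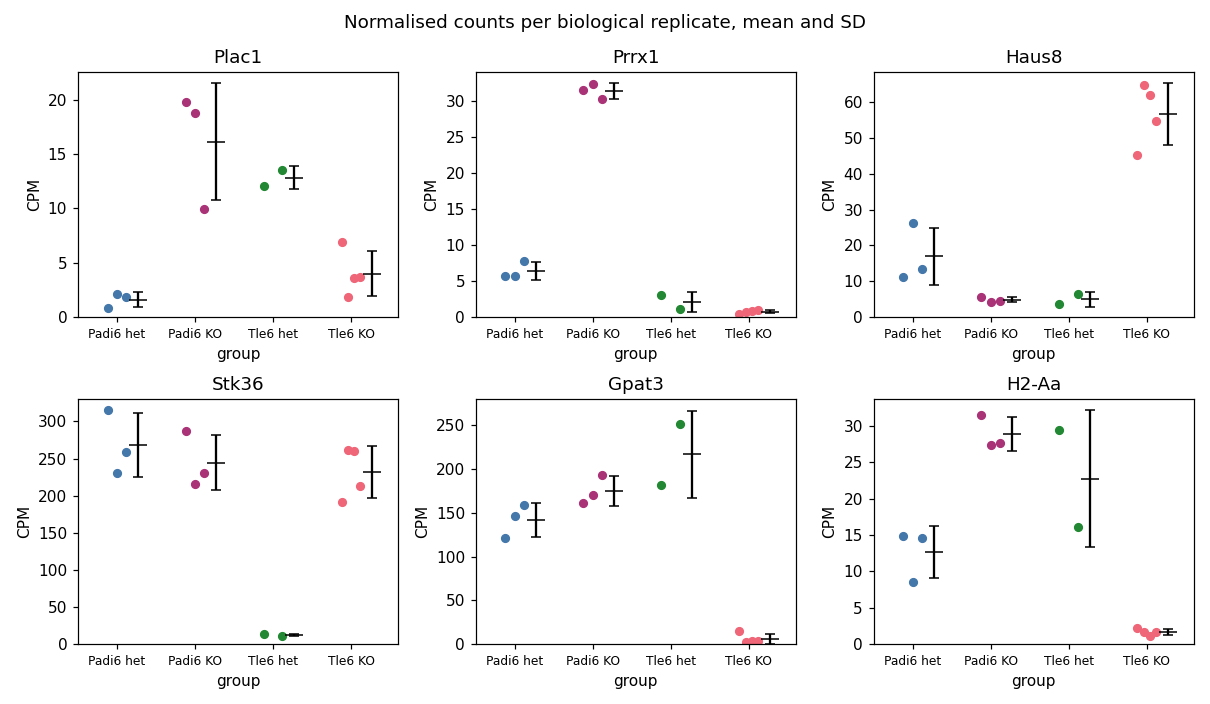
Normalised CPM for 6 of the named genes in the 4 groups, with 1 point per biological replicate, a horizontal line at the group mean and bars of 1 SD (each panel has its own linear axis from 0). Plac1 and Prrx1 are higher in Padi6 KO than in Padi6 het, Stk36 stands at 12.5 CPM in Tle6 het and at 192 CPM or more in every replicate of the other groups, and Haus8 and H2-Aa change in opposite directions in the 2 lines.

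Tle6 was likewise the lower gene of the 9 in the subcortical maternal complex and lattice list of its line, and the other 8 did not pass (1 lower adjusted over the list alone), although Zbed3 did with a spread shared by both lines (adjusted p = 0.0436). Log2 fold changes were -0.55 ± 0.21 (SE) for Zbed3, -0.40 ± 0.19 for Nlrp5, -0.38 ± 0.20 for Nlrp4f, -0.16 ± 0.22 for Padi6, -0.13 ± 0.28 for Nlrp14, -0.08 ± 0.18 for Ooep, -0.05 ± 0.23 for Nlrp2 and 0.68 ± 0.31 for Khdc3, with Nlrp14, Ooep and Nlrp2 turning positive when libraries were scaled by total count only. Khdc3 was at 0.17 without het replicate 2 and 1.34 without het replicate 1. Of 12 NLRP family genes none passed over all genes, 11 had negative values and Nlrp4a, one of a near-identical group, was lower when adjusted over the list alone (camera adjusted p = 0.0996, and 0.849 with an estimated correlation).

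No list passed camera in the Tle6 line, where 0 of 23 lists passed and 4 had an unadjusted p under 0.05. Fry called the subcortical maternal complex (adjusted p = 1.38e-03), a list that holds the targeted gene Tle6 itself, and meiotic maturation (adjusted p = 0.0488, camera adjusted p = 0.246). In the meiotic maturation list, Smc1b fell from 36.9 ± 0.885 to 15.5 ± 2.43 CPM (log2 fold change -1.26 ± 0.21, adjusted p = 0.0266, and 0.0709 without library B of het replicate 2) and 32 of 33 did not pass (1 lower adjusted over the list alone). Hspa1b was the risen gene of 26 in the unfolded protein and heat shock list, with 25 not past (1 higher adjusted over the list alone), and Myo10 that of 25 oocyte actin genes, with 24 not past (1 higher adjusted over the list alone).

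The remaining lists had no member past the test over all genes in Tle6 KO. Of 33 SCF and E2 genes, Fbxo5, an inhibitor of the anaphase-promoting complex, Fbxw7 and Fbxw18 were lower when adjusted over the list alone. Of 26 genes of small RNA pathways, Dicer1, the enzyme that makes small RNAs, and Mael were lower and Tdrd6 higher when adjusted over the list alone. Dicer1 stood at 684 ± 199 CPM in KO and 1479 ± 130 CPM in het (adjusted p over all genes 0.0678). Adjusted over the list alone, Tubg2 was higher among 17 tubulins and Sgce lower among 23 imprinted genes, and Ptch1 was higher and Dcn, Col3a1 and Pdgfra lower among 9 theca and stroma genes. Ribosomal protein genes had 82 measured members and 60 positive values (median 0.19, camera adjusted p = 0.246), and oxidative phosphorylation had 74 members and 53 positive values (median 0.20, camera adjusted p = 0.336), with 0 adjusted over the list alone in both. No member was past adjusted over the list alone in the lists of DNA methylation (20 measured), oocyte identity (29), maternal mRNA storage (31), mitochondrially encoded genes (12), proteasome (44), autophagy and lysosome (29), p53 targets (19), 2-cell transcripts (10), PADI family (3), granulosa and cumulus (25) and blood and immune cells (3). Their medians ran from -0.44 for blood and immune cells to 0.14 for granulosa and cumulus. Counted list by list, 4 members passed over all genes and 17 adjusted over the list alone; these were 3 and 11 without library B of het replicate 2, with no NLRP, SCF, small RNA or imprinted member among the 11, and 6 and 27 without library A.

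For Tle6 KO against het, edgeR's quasi-likelihood test covered 20276 genes, of which 329 had an adjusted p under 0.05 and 3852 an unadjusted p under 0.05. Scaling by total count only moved the median log2 fold change of all genes from 0.05 to 0.20 and gave 158 higher and 144 lower genes. The count of 329 was 57 with the replicate number as a block, 119 to 129 without KO replicate 2, 3 or 4 and 118 with library A alone. It was 1447 with no filter, 1732 with DESeq2, 2061 with a spread shared by both lines and 1231 with all 9 libraries as separate samples.

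**Figure D3:**
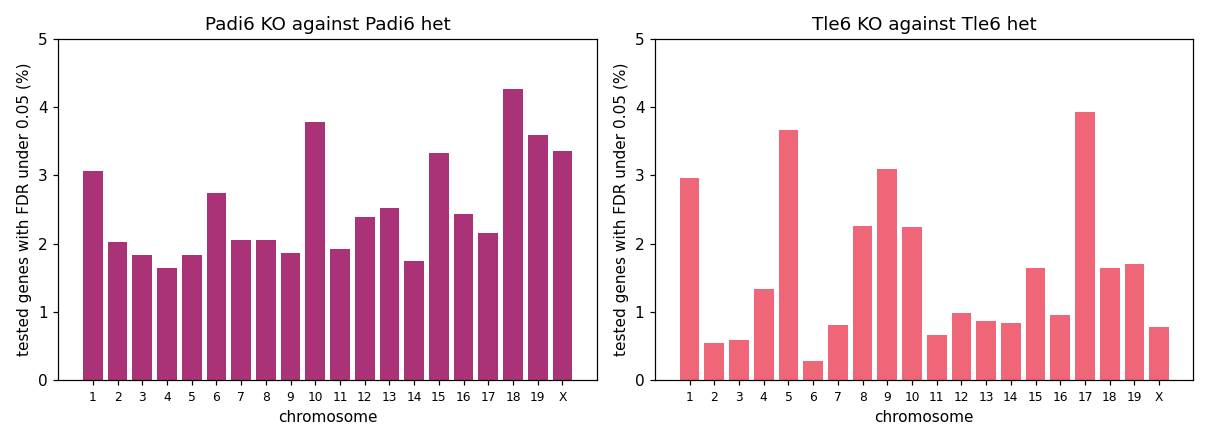
Percent of tested genes on each chromosome with an adjusted p under 0.05, for Padi6 KO against Padi6 het (left) and Tle6 KO against Tle6 het (right), with 1 bar per chromosome on a linear axis from 0. In the Tle6 line the share is 3.93% on chromosome 17 (0.753% without library B of het replicate 2) and 3.67% on chromosome 5 (1.92% without it) against 0.287% on chromosome 6, and in the Padi6 line it is 4.27% on chromosome 18 and 3.78% on chromosome 10. Without library B all calls in the Tle6 line fall from 329 to 120, so shares fall with them. Chromosome 5 holds 49 of the 329 and 25 of the 120, and chromosome 17 holds 37 and 7.

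Few genes were called in the same direction in both knockouts. With simulated 2-fold changes recovered at 63% in the Padi6 line and 14% in the Tle6 line, shared changes of that size could be missed. Dclk3, a kinase gene, was higher in both (log2 fold change 0.88 ± 0.18 SE in the Padi6 line and 1.33 ± 0.26 in the Tle6 line). Smc1b was lower in both (-0.49 ± 0.11 and -1.26 ± 0.21), as was Lrrtm3, a transmembrane protein gene (-0.80 ± 0.13 and -1.41 ± 0.27). Without library B of Tle6 het replicate 2, Dclk3 and Smc1b lost their call in the Tle6 line (adjusted p = 0.0574 and 0.0709) at log2 fold changes of 1.72 and -1.15. Without library A, Dclk3 and Lrrtm3 lost theirs (0.109 and 0.0661) at 1.05 and -1.35, so none of the 3 genes kept its call in both cases. Among the 17628 genes tested in both lines, independent lists of these sizes would share 1.56 higher and 1.43 lower genes, against 1 and 2 found. More genes were called in opposite directions. Higher in Padi6 KO and lower in Tle6 KO were 14 genes, against 3.13 for independent lists: Arid5b, Dusp6, Epha7, Erbb3, Frk, Gm39154, Grb7, H2-Aa, Rnf144a, Sox6, Tcf4, Vldlr, Zfp521 and Zfp931. Haus8 and Rad51d were lower in Padi6 KO and higher in Tle6 KO, against 0.713 for independent lists. Without library B of Tle6 het replicate 2 these counts were 3 (Grb7, Rnf144a and Zfp931, against 0.992) and 1 (Haus8, against 0.272), and without library A they were 14 against 2.92 and 2 against 0.726.

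The receptor gene Erbb3 had log2 fold changes of 1.31 ± 0.27 (SE) in the Padi6 line and -1.93 ± 0.22 in the Tle6 line, and the transcription factor gene Sox6 had 1.13 ± 0.25 and -2.45 ± 0.30. These opposite genes were not covered by the naming rule and were singled out after their values were seen. Genes lower in Tle6 KO moved upward as a set in the Padi6 line (191 genes, median log2 fold change 0.10, fry adjusted p = 0.0408 over 4 sets, but 0.52 without library B of Tle6 het replicate 2 and 0.0677 without library A), while the other 3 sets did not pass (adjusted p = 0.112 for genes higher in Padi6 KO, 0.380 for genes lower in Padi6 KO and 0.805 for genes higher in Tle6 KO). Log2 fold changes of the 2 lines correlated across genes at Pearson's r = -0.074 and Spearman's rho = -0.055, as a description, since genes are not independent replicates. The count of 3 shared genes was 1 (Lrrtm3) without library B of Tle6 het replicate 2. Without library A it was 2 (Smc1b and, not among the 3, Gm33424). It was 62 with DESeq2 and 53 with no filter. These settings called more genes in the Padi6 and Tle6 lines, 1322 and 1732 with DESeq2 and 1625 and 1447 with no filter. What independent lists of these sizes would share was not computed, so 62 and 53 do not show more sharing. Leaving out single Padi6-line replicates gave from 0 (het replicate 3) to 2 (het replicate 2).

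The difference between the Padi6 effect and the Tle6 effect was tested directly over all 12 biological replicates, and 924 genes passed, with the Padi6 effect the more positive for 644 and the more negative for 280. This test used a spread shared by both lines, although the Tle6 line varied more (common biological coefficient of variation 0.361, against 0.203). Within the lines, the same sharing moved the Padi6 count from 440 to 60 and the Tle6 count from 329 to 2061. No alternative gave each line its own spread in the test of the difference. Skint5 had a difference of 11.09 on the log2 scale and Skint6 of 8.40, both set by levels near 0 in Tle6 KO. Without library A of Tle6 het replicate 2 these were 10.50 (adjusted p = 0.0106, against 7.18e-08) and 7.87 (adjusted p = 0.0185). D5Ertd577e stood at 48.3 ± 1.97 CPM in Padi6 het, 44.1 ± 4.13 in Padi6 KO, 0.216 ± 0.144 in Tle6 het and 44.1 ± 7.38 in Tle6 KO (difference -7.75 ± 0.40 SE, adjusted p = 1.16e-07). Stk36 stood at 253 ± 44.1, 231 ± 37.0, 13.5 ± 2.05 and 243 ± 36.5 CPM in the same order (-4.30 ± 0.28), and Plcl1 at 15.6 ± 0.299, 10.6 ± 2.89, 0.0563 ± 0.0796 and 13.5 ± 1.38 CPM (-8.31 ± 0.64). For these 3 genes the Tle6 het group stood apart and the other 3 groups lay close together. The difference for Plcl1 was -7.43 without Tle6 het replicate 1 and -13.28 without het replicate 2, and that for D5Ertd577e -8.70 without het replicate 2. Skint6 was at 7.75 without Tle6 het replicate 1 and 10.75 without Tle6 KO replicate 2.

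Haus8 stood at 15.9 ± 7.19 CPM in Padi6 het and 4.53 ± 0.692 in Padi6 KO, but at 5.33 ± 2.17 in Tle6 het and 59.5 ± 9.08 in Tle6 KO (difference -5.29 ± 0.47). Rad51d had a difference of -3.48 ± 0.27, Padi6 of -6.02 ± 0.28, H2-Aa of 5.02 ± 0.42 and Cfap58, a gene of motile cilia, of 3.51 ± 0.32. No list passed camera for the difference (0 of 23, smallest adjusted p = 0.254, 3 with an unadjusted p under 0.05), while fry called 3. These were the subcortical maternal complex (adjusted p = 1.19e-03) and the PADI family (1.71e-03), which hold targeted genes, and the p53 targets (0.0202, with a camera adjusted p = 0.254 and 0.98 with an estimated correlation). The test covered 21392 genes, of which 4432 had an unadjusted p under 0.05. Scaling by total count only gave 392 more positive and 417 more negative genes. The count of 924 was 382 without library B of Tle6 het replicate 2 and 1234 without library A, 2078 with no filter, 567 at a mean of at least 5 CPM and 2051 with DESeq2, and on leaving out single replicates it ran from 406 without Padi6 het replicate 3 to 1465 without Tle6 KO replicate 1. Gene and strain background differ together between the lines, so this test does not separate them.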

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

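The tests of gene neighbourhood and of the nearer het level were chosen only after the result was seen, and the GC correction and leaving out a library of Tle6 het replicate 2 were added after the data had been seen. In Tle6 KO, the only group large enough for such a check, the highest value of 3 genes stood far from the rest (genes with 3 counts or fewer in each replicate were left out). Replicate 1 had 1.09 CPM of Pknox2, 15.2 CPM of Gpat3 and 14.8 CPM of Arid5b. These are 3 of 38 values tested, where chance gives about 1 in 20. Without KO replicate 1 the log2 fold changes were -8.39 for Pknox2, -6.03 for Gpat3 and -6.47 for Arid5b.

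The effects of the 2 knockouts differed for 924 genes (4.32% of those tested) by the test of the difference itself, which used a spread shared by both lines. Among them were 37 named genes, a number that the naming rule raises because it picks genes with large changes in a line or small p in the difference. All values are the Padi6 effect minus the Tle6 effect on the log2 scale. The targeted genes differed by -6.02 for Padi6 and 2.33 for Tle6. Of the genes higher in Padi6 KO, Plac1 differed by 5.09, Stambpl1 by 4.53, Usp17le by 4.18, Prrx1 by 3.83, Meioc by 3.48, Selenop by 3.22, Has2 by 2.86, Plk2 by 2.47, Ahi1 by 2.46, Dirc2 by 1.89, Arrdc3 by 1.72 and Dnajb9 by 1.33. Of those lower in Padi6 KO, Haus8 differed by -5.29, Rad51d by -3.48, Atf4 by -1.19 and Ppm1l by -1.08. Among genes higher in Tle6 KO the differences were -10.67 for Defb41, -8.31 for Plcl1, -7.75 for D5Ertd577e, -6.50 for Coro2b, -4.30 for Stk36, -3.76 for Myo10, -3.11 for Clcn7 and -2.99 for Upk3b. Among genes lower in Tle6 KO they were 11.09 for Skint5, 8.40 for Skint6, 6.12 for Pknox2, 5.93 for Arid5b, 5.46 for Gpat3, 5.02 for H2-Aa, 4.31 for Meiob, 3.81 for Smg9, 3.51 for Cfap58, 2.93 for Sept3 and 2.53 for Gpaa1. Fitted values of genes near 0 counts in a group (Skint5, Skint6, Defb41 and Plcl1) depend on the prior count.

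Genes past the test between Tle6 KO and Tle6 het lay close together in the genome. Of the 329, 117 had another such gene within 5 tested genes. A permutation test with 1000 random draws of as many tested genes, matched on expression, gave a median of 49 and at most 81 (p = 0.000999, the smallest these draws can give). The same held without library B of het replicate 2 (33 of 120, at most 22 in the draws) and without library A (105 of 316, at most 73). After removal of each library's GC trend 266 of the 329 still passed, which argues against GC content as the whole cause. Stretches of DNA from another strain that differ between the het and KO animals may account for part of these genes, although both groups are labelled C57BL/6J and neighbouring genes that are regulated together, or similar genes such as those around D5Ertd577e, would also lie close. An effect of the knockout that does not depend on strain stays open, since the Tle6 het level was nearer than the KO level to the Padi6 het level for 55.8% of the genes (bootstrap interval 51 to 61.4%), but the interval was 49 to 67.2% without library B and 43.1 to 55.2% without library A.

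Spike-in transcripts, which no comparison used, had counts above 0 in every library and very uneven ones. In the Padi6 line there were 7116, 7053 and 40 counts in het replicates 1, 2 and 3 and 13772, 4413 and 4009 in KO replicates 1, 2 and 3. The Tle6 line had 45 and 27 in libraries A and B of het replicate 1, 30 and 22 in those of het replicate 2, 18, 25 and 42 in KO replicates 1, 2 and 3, and 20 and 5 in libraries A and B of KO replicate 4. Whether spike-ins were added to each library is not given in the sources used here.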

How the results depend on the processing

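Leaving out a library of Tle6 het replicate 2, keeping its libraries apart and removing the GC trend were chosen only after the data had been seen. The fold changes of Padi6 in the Padi6 line and of Tle6 in the Tle6 line kept their direction and call under every alternative run. Of 656 values for the 33 named genes past the test in the Padi6 line, 514 kept direction and call and 142 kept the direction but lost the call. In the Tle6 line these were 493 and 73 of 566 values for 23 genes, and for 10 genes in the difference all 230 kept both. The self-test's low recovery of 2-fold changes in the Tle6 line and the difference limits what fewer replicates can show. When a Tle6 het replicate was left out, the remaining one was assumed to vary like the KO group. The cause was not tested for the values that follow, except where fewer samples or genes entered.

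With no filter, 1625 genes passed in the Padi6 line, 1447 in the Tle6 line, 2078 in the difference and 53 in both lines in the same direction. With DESeq2 these were 1322, 1732, 2051 and 62. What independent lists of these larger sizes would share was not computed, so 53 and 62 do not show more sharing. A spread shared by both lines gave 60, 2061 and, in both lines, 5. A 2-fold minimum gave 262 in the Padi6 line and 0 in both lines. A mean of at least 5 CPM gave 567 in the difference and 6 in both lines. Without library B of Tle6 het replicate 2 there were 120 in the Tle6 line, 382 in the difference and 1 in both lines, without library A 316, 1234 and 2, and with its libraries apart 179, 339 and 1. Library A alone gave 118 in the Tle6 line, and all 9 libraries as separate samples gave 1231. The correlation of effects across genes was -0.04 with no filter, -0.106 at 5 CPM, -0.011 without library B and -0.101 without library A.

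Leaving out single replicates gave 61 to 258 genes in the Padi6 line, 119 to 292 in the Tle6 line, 406 to 1465 in the difference and 0 to 2 in both lines, correlations of -0.097 to -0.017, and 1 to 2 lists in the Padi6 line and 0 to 1 in the Tle6 line. The 1 list of the Padi6 line became 0 with an estimated correlation (0 with an unadjusted p under 0.05) or without mitochondrially encoded genes, and 2 with fry, no filter or 5 CPM. The 0 lists of the Tle6 line became 2 with fry and 1 at 5 CPM, with the replicate block on thinned counts, or with the libraries of het replicate 2 apart.

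With the replicate number as a block, 859 genes passed in the Padi6 line (899 on thinned counts), 57 in the Tle6 line (113 on thinned counts) and 0 in both lines (4 on thinned counts). Of the 23 named genes past the test in the Tle6 line, 9 lost their call with the block and 6 with the block on thinned counts. Deviations of KO and het libraries of the same number correlated at 0.461, 0.038 and 0.230 in the Padi6 line, where KO replicate 3 went best with het replicate 2 (0.327), so its numbers were not taken to pair the samples. The Tle6 line shares only 2 numbers, at 0.213 and 0.330, too few to show pairing by number. KO replicate 4 also went with het replicate 1 (0.459), and KO replicate 3 with het replicate 2 (0.329). With 2 het replicates the deviations mirror each other, so a KO replicate that goes with one goes against the other. KO replicates 3 and 4 have no het replicate of their number, so the block by number does not cover these sets. No fit had a block for them.

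Zbed3 in the Tle6 line gained a call with a spread shared by both lines (-0.60). Genes that changed sign were never past the test. In the Tle6 line, total count scaling gave 0.041 for Nlrp14, 0.070 for Ooep and 0.121 for Nlrp2, and GC removal 0.035 for Nlrp14 and 0.049 for Nlrp2. Nlrp2 was at 0.031 at 5 CPM, 0.024 with the block and 0.045 with the block on thinned counts, and Nlrp14 at 0.069 without library A of het replicate 2. Leaving out single replicates gave -0.45 to 0.21 for Nlrp14, -0.30 to 0.11 for Ooep, -0.31 to 0.20 for Nlrp2 and -0.398 to 0.059 for Padi6 there, and -0.163 to 0.013 for Nlrp4f in the Padi6 line.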

Other observations

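The tests of technical pairs against sampling noise and for separate samples, of gene neighbourhood and of chromosome shares were chosen only after the result was seen, and the GC correction and leaving out a library of Tle6 het replicate 2 were added after the data had been seen. Genes past the test in Tle6 KO were spread unevenly over chromosomes (chi-square 156, against at most 48.7 in 1000 draws, p = 0.000999, the smallest these draws can give), with 3.93% of tested genes on chromosome 17, 3.67% on chromosome 5, 3.09% on chromosome 9 and 0.287% on chromosome 6. Without library B of Tle6 het replicate 2 the chi-square was 106 (at most 44.7 in the draws) and the share was 0.753% on chromosome 17, 1.92% on chromosome 5 and 1.08% on chromosome 9, and without library A the chi-square was 216 (at most 46.6), with 5.47% on chromosome 17. Without library B all calls fell from 329 to 120, so shares fell with them. Chromosome 5 held 49 of the 329 and 25 of the 120, chromosome 17 held 37 and 7, and chromosome 9 held 35 and 12. In the Padi6 line the chi-square was 36.5, against at most 41.5 in the draws (p = 0.00699). On chromosome 5, 2010109A12Rik, Ccng2, C87414, Gm3106, AA792892, Gm6205, Gm3259 and D5Ertd577e formed a run of 8 such genes, 7 of them higher in Tle6 KO, several of which belong to a family of similar genes. Another run of 8 on that chromosome held Slc10a6, Hsd17b13, Abcg3, Gbp8 and Lrrc8b. Of the 40 tested genes on each side of Tle6, Gm32687 and 1190007I07Rik passed, against 1.3 from the overall share, and on each side of Padi6 Ephb2 and Gm13041, against 1.93.

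Libraries A and B of Tle6 het replicate 2 differed far beyond sampling noise, with a mean chi-square per gene of 972 against at most 6.31 in the other technical pairs. The ratio went with GC content, as the median log2 ratio of B to A ran from -0.15 in the lowest to -1.01 in the highest of 10 GC classes. In the other technical pairs these medians ran from 0.066 to -0.094 and from 0.084 to -0.120. Spearman's rho of the ratio with GC was -0.244 here, against -0.505 and -0.558 in those pairs. Whether GC bias or unlike samples made this trend was not tested. Of the 42 genes at an 8-fold or larger ratio, 36 stayed there after the GC trend was removed, which argues against GC as the whole cause. Libraries from separate samples are a candidate explanation, as 7 genes stood at 10 CPM or more in one library with 3 counts or fewer in the other, against 0 such genes in the other pairs. Skint5 had 24.3 CPM in A and 0 counts in B, and Bfsp1, a lens filament gene, 39.7 CPM in B and 0 counts in A. Il20ra, Skint5 and Prr15l stood at 10 CPM or more in A and in both libraries of het replicate 1, with 2 counts or fewer in B. In the Tle6 KO libraries they stood at 0.233 CPM or less, so B was like KO for these genes. Tle6 was at 234 CPM in B, below the other Tle6 het libraries (378 to 600) but above the KO libraries (98.2 or less). Across genes B correlated at 0.934 and 0.940 with the libraries of het replicate 1 and at 0.887 to 0.930 with KO libraries. Pak3 and Krt17 stood at 10 CPM or more in A alone of the 15 libraries, and Bfsp1 and D430041D05Rik in B alone. Which of the libraries, if either, belongs to another sample stays open.

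Of the 440 genes past the test in Padi6 KO, 409 still passed after removal of the GC trends, which argues against GC content as the whole cause. Strain haplotypes that differ between the animals cannot be told apart from other sources here, as 113 of the genes had another such gene within 5 tested genes, above the median of 95 in a permutation test with 1000 draws and below their maximum of 132 (p = 0.0669), and among protein-coding genes with a symbol 110 of 365 did, against a median of 88 and a maximum of 119 (p = 0.027). Only 10 splits of the 6 samples into 3 and 3 exist, too few for a share under 0.05. By edgeR 440 genes passed in the real split, the 1 split with as many, and 0 in each of the others, where up to 1908 had an unadjusted p under 0.05 against 3399 in the real split. As many lists as the real 1 were called in 6 of the 10 splits, with 3 as the highest of the others.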
